A study of Mus musculus with 24 samples.

How the data were processed

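Dorsal root ganglia of mice from 3 strains, labelled C57, CAST and DBA, were profiled by RNA sequencing, either naive or 5 days after crush of the sciatic nerve. The series design calls the libraries of each group biological quadruplicates, which gives 6 groups of 4 libraries and 24 libraries in all. The treatment protocol in the labels speaks of crush against sham injury, whereas the sample labels call the uninjured ganglia naive. They are called naive here, and whether a sham operation was done is not settled by the labels. Other strains that the series design counts were not analysed here.

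Per the labels' protocols, RNA was extracted with Trizol as total RNA and libraries were made by a standard Illumina protocol. Per the submitters' processing notes, reads were aligned with STAR 2.3.0 to the mouse genome build mm10. The counting tool, its annotation, the use of strand and the treatment of reads that map to several places are not given in the sources used here. The authors deposited FPKM values (fragments per kilobase of gene and per-million reads), 1 value per gene and library for 38215 genes. All 24 libraries held the same values in their own file and in the series table.

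The FPKM values were examined before any test was chosen. Of the gene IDs, 36345 (95.1%) were found in the GENCODE M21 annotation of mm10. When each value was multiplied by the genomic span of its gene, introns included, low values fell on whole multiples of a unit that was shared by all genes of a library. Of the values worth 0.5 to 100 reads, 67.9% were whole within 0.05 reads, against 10.0% expected by chance. The kilobase term of the deposited FPKM was therefore read as the full span of the gene. The steps gave library totals of 51.39 to 145.46 M reads (M stands for 1e6 reads, and CPM below for estimated reads per 1e6 reads), with a median of 107.1 M. They also gave estimated reads per gene, which were used for filters and for alternative tests. Levels of genes with different intron content cannot be compared on this scale, and a gene with a long span has a low FPKM even when many reads cover it.

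The fixed plan named a test on raw counts and, in case the files held none, limma on log2(FPKM + 1). The deposited values are FPKM, so the written fallback was used. Genes with at least 10 estimated reads in at least 4 libraries were kept, or an FPKM of at least 0.1 for IDs without a span. This left 27047 genes and removed 11168. No scaling was added to the per-million scaling of the authors. A linear model with the 6 group means was fitted to all 24 libraries, so that every comparison shared an estimate of the spread. The fit used limma 3.58.1 with statmod 1.5.0 in R 4.3.3, with a mean-dependent, robust empirical Bayes variance. P-values were two-sided and adjusted by the Benjamini-Hochberg method within each of 11 contrasts, and a gene was called at an adjusted p under 0.05. Adjusted p-values in the text are from limma unless another test is named, and they measure the spread between animals labelled as biological quadruplicates. Log2 fold changes are on the log2(FPKM + 1) scale with their standard error (SE), and this scale understates the change of genes with low FPKM. For named genes the mean FPKM of each group is given with its standard deviation (SD, n = 4), or the ratio of the mean FPKM values.

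The contrasts were injured against naive within each strain, the differences between strains of that response (interaction contrasts), naive ganglia of each pair of strains, and injured CAST ganglia against the mean of injured C57 and DBA ganglia. A gene was counted as shared when it was called in the same direction in the crush contrast of all 3 strains.

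Lists of genes were fixed before the data were examined. Of these, 26 were tested and 437 of their 443 genes passed the filter, and a list of sex-linked genes was only described per library. The lists cover injury-induced transcription factors, growth-associated genes, injury-induced neuropeptides, nociceptor genes, voltage-gated channels, pan-neuronal genes, activin, BMP and TGF-beta signalling, gp130 cytokine signalling, neurotrophic factors, cholesterol synthesis, interferon response, antigen presentation (MHC), cell cycle, handling stress and markers of non-neuronal cell types. The activin list and Inhba were written with knowledge of the study and are not independent evidence. Lists were tested against all other genes with camera in limma, at a preset inter-gene correlation of 0.01, and p was adjusted over the 26 lists of a contrast. Each was tested again with the correlation estimated from the residuals. Each was also tested with fry, which asks whether the list changed at all and not whether it differed from other genes. Beside the number of members called over all genes, the number "adjusted over the list alone" is given.

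Named genes were also chosen by a rule fixed before the data were examined. Per contrast, the rule took the 10 largest rises and 10 largest falls among called genes with a mean of at least 1 CPM and a proper gene symbol, whose libraries on both sides did not overlap where only 2 groups were compared. It added 17 genes fixed by name, and for each list the called members with the largest changes in each direction. Positions are from GENCODE M21 on mm10.

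The procedure was tested on simulated libraries drawn from the means of the naive groups, the spread within groups and the library totals of the real ones, with known folds put into the injured CAST libraries. In 8 simulations of the CAST crush comparison with 8000 changed genes, 92.3% to 93.8% of 1.5-fold changes and 98.4% to 99% of 4-fold changes were recovered among at least 25554 genes, and 4.1% to 4.9% of the calls were false. For the contrast of CAST with the mean of the other strains, 88.3% to 89.9% of 1.5-fold changes were recovered, and 3.5% to 4.1% of calls were false. With only 200 changed genes the share of false calls was 10.6% to 21.6% in the CAST crush comparison. It was 1.2% to 8.2% when only the 2 groups of that comparison entered the fit. For the contrast of CAST with the mean of the other strains, fitted to all libraries, it was 6.4% to 13.1%. Calls from the fit of all libraries were therefore more permissive than their threshold where few genes were changed. In a simulated list of 20 genes raised in the CAST crush comparison, camera called the raised direction, and 20 unchanged genes were not called. The simulated genes were drawn independently, with 1 spread per gene in all groups. They therefore do not test camera on lists whose genes move together, or the fit where groups differ in spread.

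Libraries of a group correlated at r = 0.983 to 0.994 across genes on the log2 scale, and no pair of libraries differed by as little as sampling noise alone would give (mean chi-square per gene from 2.47 to 8.56). A read shared by near-identical genes cannot be placed from these values. For example, Ubb had 254135 estimated reads per library on average and the pseudogene-like Gm1821 had 304684. Genes with copies, overlapping genes and antisense partners are uncertain for the same reason. The alternatives were median-of-ratios and upper-quartile scaling, no filter, a filter at more than 1 CPM in at least 4 libraries, a pseudocount of 0.1, a fit of only the groups of the contrast, a block for the replicate number, a 2-fold minimum on the log2(FPKM + 1) scale, and leaving out each library in turn. A test designed for raw counts was planned as a further alternative and was not run, because the deposited values are not counts. Added after seeing the data were log2 of CPM plus 0.5 (which removes the span term), voom in limma on the estimated reads, and a fit without 3 libraries. Those are injured C57 replicate 3, which had the lowest total (51.39 M reads), naive C57 replicate 1, which had the highest value of its group on principal component 4, and naive DBA replicate 3, which held skeletal muscle transcripts. Sequences shared between genes were searched as 31-mers of the longest GENCODE M21 transcript of each gene, and a gene was taken as a copy of another when it held at least 20% of the 31-mers of that gene. The search used Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.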

Results

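Gene expression was measured in dorsal root ganglia, which hold the cell bodies of the sensory neurons whose axons run in the sciatic nerve. The series title concerns regeneration of axons in the injured central nervous system of CAST/Ei mice, and the ganglia were taken from mice labelled C57, CAST and DBA, either naive or 5 days after crush of the sciatic nerve. Each of the 6 groups held 4 libraries. Library totals recovered from the values averaged 99.65 M reads in naive C57, 98.7 M in injured C57, 105.91 M in naive CAST, 124.3 M in injured CAST, 98.25 M in naive DBA and 108.51 M in injured DBA ganglia. The lowest total was 51.39 M, in injured C57 replicate 3, and 62.9% to 64.8% of the reads of a library lay in genes. All 24 libraries carried transcripts of the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty, with at least 154 estimated reads each, and at most 28 reads of Xist, the RNA that silences an X chromosome in females.

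The first principal component held 35.3% of the variance and the second 32.2%. Libraries of a group lay together and the 6 groups were separate. Injured CAST libraries had the lowest first component, from −36.89 to −34.52, and the third component, with 11.9% of the variance, separated C57 from DBA. Naive C57 replicate 1 had the highest value of its group on the fourth component, which held 3.1% of the variance, at 16.03 against −9.97 to 3.65.

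**Figure D1:**
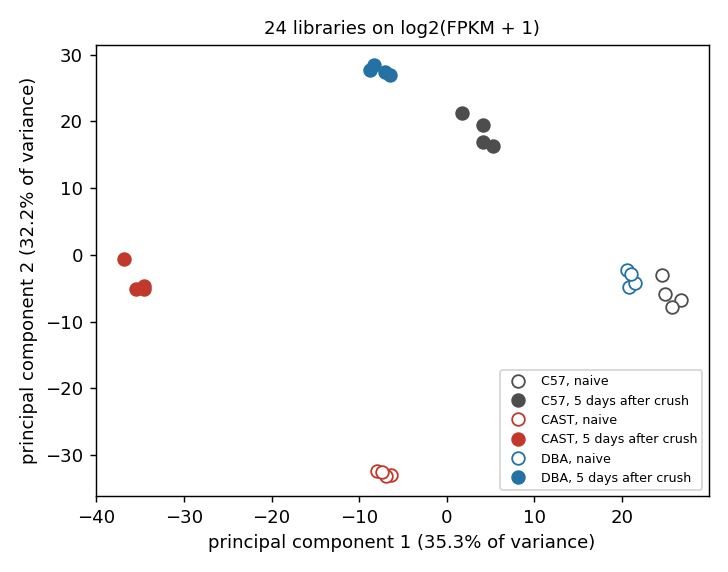
Principal components 1 and 2 of log2(FPKM + 1), each point a library, with colour for the strain, open markers for naive and filled markers for injured. The first component holds 35.3% of the variance and the second 32.2%, and the injured CAST libraries lie at −36.89 to −34.52 on the first.

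The first question was which genes changed in the ganglion after crush in each strain. Atf3, a transcription factor of injured neurons, rose in C57 from 0.288 ± 0.0444 to 18.1 ± 1.99 FPKM (SD, n = 4), which is 62.9-fold, and it rose 49.0-fold in CAST and 61.5-fold in DBA. Sprr1a, a small proline-rich protein that promotes axon growth, rose from 0.64 ± 0.437 to 461 ± 35.9 FPKM in C57, from 2.44 ± 1.14 to 408 ± 45.3 in CAST and from 0.558 ± 0.185 to 546 ± 9.3 in DBA (SD, n = 4). The neuropeptide galanin, encoded by Gal, rose 40.5-fold, 122-fold and 157-fold in C57, CAST and DBA. Sensory neuron genes fell, among them Scn10a, the sodium channel Nav1.8 of nociceptors, which was 1.93-fold lower after crush in C57, 2.21-fold in CAST and 2.94-fold in DBA.

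In mm10 coordinates, Atf3 lies on the minus strand of chromosome 1 from 191170296 to 191218039, Sprr1a on the minus strand of chromosome 3 from 92483952 to 92485895, and Gal on the minus strand of chromosome 19 from 3409915 to 3414544. All 3 are annotated as protein-coding. The log2 fold change of Atf3 was 3.89 in C57 (SE 0.066, adjusted p = 2.67e-19), and that of Sprr1a was 8.17 (SE 0.175, adjusted p = 1.13e-17). Both were called in CAST and DBA as well.

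Of the 26 growth-associated and cytoskeletal genes, 25 rose and 0 fell in C57, 25 rose in CAST and 24 in DBA, with the same counts in C57 when adjusted over the list alone (camera adjusted p = 4.94e-28, 6.85e-20 and 2.65e-20). The call was kept with an estimated correlation in each strain (adjusted p = 0.00421, 0.0224 and 0.0125). Gap43, a protein of growth cones, rose 3.91-fold, 4.5-fold and 5.44-fold in C57, CAST and DBA, and the stress-induced gene Gadd45a rose 8.54-fold, 10.1-fold and 12.8-fold. Gpr151, an orphan receptor, rose 84.9-fold, 11.9-fold and 62.3-fold. Of 17 injury-induced transcription factors, 14 rose and 2 fell in C57 and in CAST, and 15 rose and 2 fell in DBA (camera adjusted p = 8.53e-09, 2.86e-07 and 1.02e-07, with adjusted over the list alone the same 14 and 2 in C57). With an estimated correlation the adjusted p was 0.0278 in C57, 0.0593 in CAST and 0.0398 in DBA. Sox11, a factor of developing neurons, rose 8.24-fold, 7.54-fold and 8.62-fold, Jun rose 2.59-fold, 2.87-fold and 4.01-fold, and Smad1 rose 2.2-fold, 2.56-fold and 2.3-fold.

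Among 14 injury-induced neuropeptides and receptors, 9 rose and 2 fell in C57 (10 and 2 adjusted over the list alone), 9 rose and 3 fell in CAST, and 11 rose and 2 fell in DBA (camera adjusted p = 1.79e-07, 6.8e-05 and 9.19e-08). With an estimated correlation the adjusted p was 0.021 in C57, 0.0593 in CAST and 0.0125 in DBA. Npy rose from 0.0427 ± 0.0121 to 14.6 ± 0.329 FPKM in C57 (SD, n = 4), neurotensin (Nts) rose 15.3-fold, 8.24-fold and 24.6-fold, and corticotropin-releasing hormone (Crh) rose 117-fold, 86.5-fold and 183-fold. Somatostatin (Sst), a peptide of itch neurons, fell in the same comparison and was 1.84-fold lower in C57, 5.04-fold in CAST and 2.75-fold in DBA. The vasoactive peptide gene Vip was near the floor, at 0.0114 ± 0.00701 FPKM in injured C57 and 0.025 ± 0.00843 in injured DBA ganglia (SD, n = 4). It was called in DBA (adjusted p = 0.00178) and not in C57 (adjusted p = 0.151) or CAST (adjusted p = 0.907). Of 17 genes of gp130 cytokine signalling, 10 rose and 2 fell in C57, 12 rose and 4 fell in CAST and 13 rose and 2 fell in DBA (camera adjusted p = 3.98e-05, 0.000122 and 4.47e-05; adjusted over the list alone, 12 rose and 2 fell in C57, and 3 fell in DBA). With an estimated correlation the adjusted p was 0.147, 0.121 and 0.0871. Csf1, a growth factor of macrophages and microglia, rose 9.7-fold, 11.7-fold and 11.9-fold, and Socs3, a feedback inhibitor of this pathway, rose 2.46-fold, 3.3-fold and 4.97-fold.

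Genes of mature neurons moved the other way. Of 20 nociceptor genes, 17 fell in each strain and 3, 3 and 2 rose in C57, CAST and DBA, with 3 and 17 adjusted over the list alone in C57 (camera adjusted p = 4.25e-06, 2.65e-07 and 5.79e-08). The calls were lost with an estimated correlation (adjusted p = 0.168, 0.109 and 0.0799). Mrgprd, a receptor of non-peptidergic nociceptors, was 1.87-fold, 3.25-fold and 3.09-fold lower, substance P precursor (Tac1) was 1.81-fold, 2.27-fold and 3.08-fold lower, and Calca, which encodes CGRP, was 1.69-fold, 1.63-fold and 1.69-fold lower in C57, CAST and DBA. Among 22 voltage-gated channel genes, 14 fell and 2 rose in C57 (15 and 2 adjusted over the list alone), 17 fell in CAST and 17 in DBA (camera adjusted p = 9.47e-06, 5.08e-07 and 4.33e-06; adjusted p = 0.313, 0.183 and 0.226 with an estimated correlation). The potassium channel subunit Kcns1 was 2.01-fold, 2.75-fold and 2.28-fold lower. Of 16 pan-neuronal genes, 9, 10 and 12 fell and 2 rose in each strain (camera adjusted p = 0.000932, 5.65e-05 and 2.29e-05; adjusted p = 0.147, 0.0593 and 0.0514 with an estimated correlation; in C57, 10 fell adjusted over the list alone, and 11 in CAST). Neurotrophic factors and their receptors went both ways, with 6 higher and 9 lower of 20 in C57, 8 and 8 in CAST and 9 and 8 in DBA (camera adjusted p = 0.838, 0.979 and 0.701).

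Markers of other cells rose as well. All 20 macrophage genes rose in C57 and DBA and 19 in CAST, where 20 rose adjusted over the list alone (camera adjusted p = 1.3e-18, 2.53e-15 and 5.2e-17 in C57, DBA and CAST; adjusted p = 0.0584, 0.0606 and 0.0593 with an estimated correlation). C1qa, a complement component made by macrophages, rose from 2.17 ± 0.259 to 11.4 ± 0.837 FPKM in C57 and from 1.55 ± 0.248 to 18 ± 1.98 in CAST (SD, n = 4). Of 21 cell cycle genes, 10 rose in C57, 16 in CAST and 19 in DBA (camera adjusted p = 0.00183, 6.8e-05 and 8.83e-08; adjusted p = 0.367, 0.183 and 0.0799 with an estimated correlation; 17 in CAST adjusted over the list alone). Among 14 repair Schwann cell genes, 7, 10 and 12 rose and 2, 1 and 0 fell (camera adjusted p = 0.0168, 0.00128 and 4.33e-06; adjusted p = 0.168, 0.0593 and 0.0125 with an estimated correlation; 2 fell in CAST adjusted over the list alone). Gfap, an intermediate filament of reactive glia, rose from 0.126 ± 0.0336 to 1.69 ± 0.186 FPKM in CAST and from 0.159 ± 0.0314 to 2.39 ± 0.379 in DBA (SD, n = 4). In C57 it rose from 0.0486 ± 0.0139 to 0.181 ± 0.0301 FPKM (SD, n = 4), a log2 fold change of 0.172 (SE 0.055, adjusted p = 0.0175). Without 3 libraries chosen after seeing the data (injured C57 replicate 3, naive C57 replicate 1 and naive DBA replicate 3) the value was 0.166 (SE 0.069), and the call was lost as the SE widened (adjusted p = 0.0648). On the scale of log2(CPM + 0.5) Gfap was called in C57 (1.36, adjusted p = 6.46e-08). Of 14 fibroblast genes, 8, 12 and 12 rose (camera adjusted p = 0.00748, 0.000363 and 6.37e-06; adjusted p = 0.516, 0.311 and 0.189 with an estimated correlation; 9, 12 and 14 adjusted over the list alone). The handling-stress list was planned as a check of quality and marks no cell type. Of its 16 genes, 8, 10 and 13 rose and 2, 3 and 0 fell (camera adjusted p = 0.00787, 0.0027 and 1.5e-05; adjusted p = 0.217, 0.139 and 0.045 with an estimated correlation). It shares Atf3 with the injury-induced transcription factors. The repair Schwann cell list shares Jun with those factors and Btg2 with the handling-stress list, so these lists are not independent.

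Lists that were not called in C57 were lymphocytes (3 of 16 rose, camera adjusted p = 0.0744), neutrophils (2 of 13, 0.0828), myelinating Schwann cells (4 of 17, 0.105), oligodendrocytes and astrocytes (1 of 10 rose and 1 fell, 0.607), skeletal muscle (1 of 14 fell, 0.607), erythrocytes (1 of 9 fell, 0.835), and endothelium, satellite glia and adipocytes, each with a camera adjusted p of 0.838. In CAST 10 of 16 lymphocyte genes rose (camera adjusted p = 0.0146, and 0.123 with the filter on CPM; adjusted p = 0.369 with an estimated correlation), and in DBA 6 rose (camera adjusted p = 0.0808). The remaining cell type lists in CAST and DBA had camera adjusted p-values of at least 0.16, apart from skeletal muscle in DBA. There 4 of 14 muscle genes fell, or 12 adjusted over the list alone (camera adjusted p = 0.0179, and 0.0696 with the filter on CPM; adjusted p = 0.729 with an estimated correlation), and 2 fell without the same 3 libraries (camera adjusted p = 0.0835). Naive DBA replicate 3 held 29.1 FPKM of skeletal actin (Acta1), against 0.458 to 3.75 in the other libraries of its group. Cholesterol synthesis rose in C57, with 10 of 22 genes higher (camera adjusted p = 0.00999; adjusted p = 0.516 with an estimated correlation), and in DBA with 13 (camera adjusted p = 0.0242; adjusted p = 0.604 with an estimated correlation; camera adjusted p = 0.0517 without the 3 libraries). In CAST 5 rose and 4 fell (camera adjusted p = 0.811).

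Across all 27047 genes, 10449 were called in C57 (4901 higher and 5548 lower), 12754 in CAST (6936 and 5818) and 13563 in DBA (7128 and 6435). With upper-quartile scaling the larger share turned to lower genes in CAST (5964 higher and 6633 lower) and in DBA (6759 and 6811). With a minimum of 2-fold on the log2(FPKM + 1) scale, which understates the change of genes with low FPKM, the counts were 147, 296 and 309, with 130 higher and 17 lower in C57. In all 3 strains 7262 genes were called in the same direction, 3553 higher and 3709 lower (2948 and 2887 when only the groups of each contrast were fitted), against 615 for independent lists, and 294 genes were called in opposite directions. The responses correlated across genes at Pearson r = 0.789 between C57 and CAST, 0.871 between C57 and DBA and 0.826 between CAST and DBA (Spearman rho 0.717, 0.772 and 0.738), where genes are not independent replicates.

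**Figure D2:**
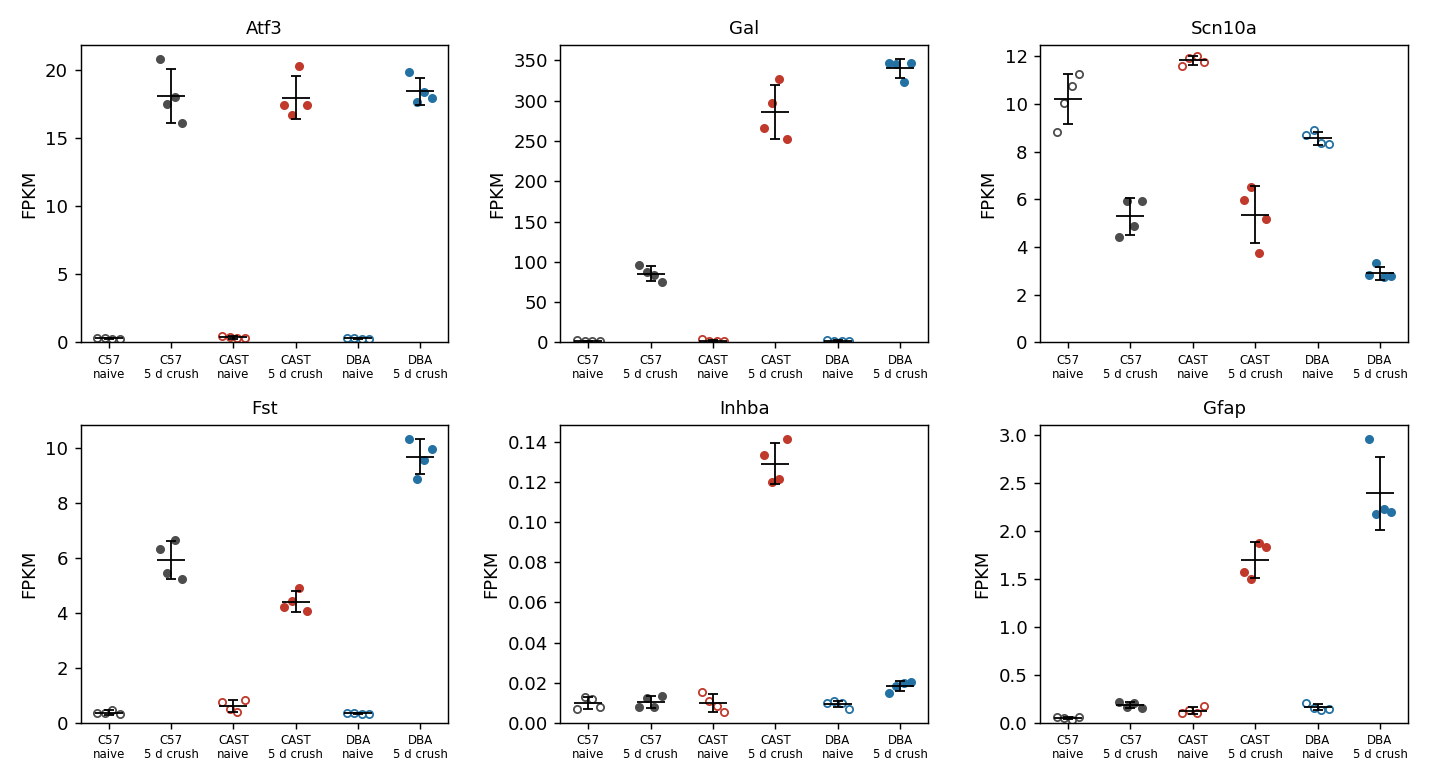
FPKM (vertical axis) of Atf3, Gal, Scn10a, Fst, Inhba and Gfap in naive and injured ganglia of the 3 strains (horizontal axis), with points for single libraries, bars for the mean and error bars for the SD (n = 4). Inhba reached 0.129 FPKM in injured CAST ganglia and 0.0102 in injured C57 ganglia.

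The next question was whether ganglia of CAST responded to crush differently from those of C57 and DBA, which was tested as an interaction. Interferon-induced genes rose in CAST more than in the other strains. Ifit1, an interferon-induced protein that binds foreign RNA, rose from 0.286 ± 0.121 to 12.6 ± 5.83 FPKM in CAST, and was at 2.03 ± 0.731 and 1.66 ± 0.353 in naive and injured C57 and at 0.656 ± 0.0506 and 1 ± 0.265 in naive and injured DBA ganglia (SD, n = 4). Isg15, a ubiquitin-like modifier, rose 22.5-fold in CAST and 2.39-fold in DBA, and stood at 2.45 ± 0.81 and 2.44 ± 0.684 FPKM in naive and injured C57 ganglia (SD, n = 4). B2m, the light chain of MHC class I, rose 5.54-fold in CAST, 2.04-fold in DBA and 1.27-fold in C57. Ifit1 lies on the plus strand of chromosome 19 from 34640871 to 34650009, and its response in CAST exceeded the mean of the others by 3.25 on the log2 scale (SE 0.265, adjusted p = 2.12e-08).

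All 21 interferon-response genes rose after crush in CAST (camera adjusted p = 2.2e-12; adjusted p = 0.165 with an estimated correlation). In DBA 8 rose, or 4 adjusted over the list alone (camera adjusted p = 0.0979), and 4 rose without the 3 libraries named above. Injured DBA replicate 3, which is not one of those, stood apart for this list. Its mean log2(FPKM + 1) was 0.86, against 0.61 to 0.64 in the other libraries of its group. The list was called in DBA on the scale of log2(CPM + 0.5) (camera adjusted p = 0.00436), and not with an estimated correlation on the main scale (adjusted p = 0.747). In C57 limma called 0, also at an unadjusted p under 0.05, and voom on estimated reads called 2 higher (camera adjusted p = 0.667). In the test of the difference, 20 of the 21 genes rose more in CAST than in the mean of C57 and DBA, with 20 adjusted over the list alone and a median of 0.80 on the log2 scale (camera adjusted p = 9.12e-24; adjusted p = 0.178 with an estimated correlation). Examples were Ifit3 (2.53), Mx2 (2.17) and Bst2 (2.17). Of 14 antigen presentation genes, 12 rose more in CAST, also when adjusted over the list alone, with a median of 0.61 (camera adjusted p = 1.88e-10; adjusted p = 0.178 with an estimated correlation), and 14 rose within CAST, 12 within DBA and 6 within C57 (camera adjusted p = 6.14e-09, 5.5e-05 and 0.00258; adjusted p = 0.0593, 0.189 and 0.367 with an estimated correlation; 14, 13 and 9 adjusted over the list alone). Among 20 macrophage genes, 11 rose more and 2 rose less in CAST, or 13 and 2 adjusted over the list alone (camera adjusted p = 4.69e-05; adjusted p = 0.834 with an estimated correlation). C1qa rose more in CAST (0.78), whereas the scavenger receptors Cd163 (−0.16) and Mrc1 (−0.20) rose less. Cholesterol synthesis had 3 of 22 genes with a lower response in CAST, or 5 adjusted over the list alone, among them Hmgcs1 (−0.24, camera adjusted p = 0.000723; adjusted p = 0.834 with an estimated correlation). The other 22 lists were not called, including growth-associated genes (3 rose more and 8 less, camera adjusted p = 0.111) and neuropeptides (4 and 5, camera adjusted p = 0.21). With an estimated correlation the adjusted p was 0.924 for both. Growth-associated genes were called without the 3 libraries (camera adjusted p = 0.029) and on the scale of log2(CPM + 0.5) (0.0287), where neuropeptides were called too (camera adjusted p = 0.0278).

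**Figure D3:**
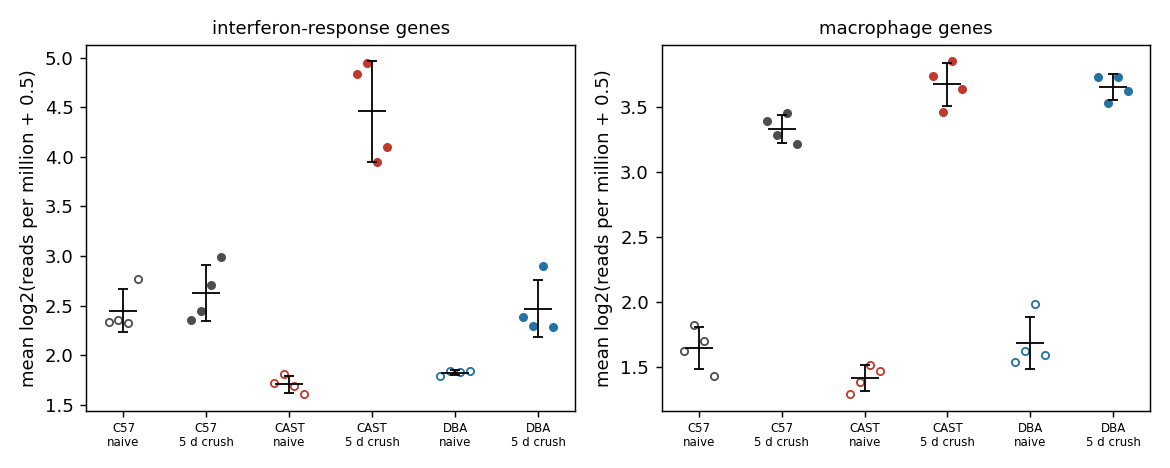
Mean log2(CPM + 0.5), from estimated reads, of the 21 interferon-response genes and of the 20 macrophage genes (vertical axes, not starting at 0) in each library, by group (horizontal axis). Interferon genes stand at 3.95 to 4.95 in injured CAST libraries and at 1.61 to 1.81 in naive CAST libraries, whereas the macrophage list is higher after crush in all strains.

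Single genes differed between CAST and the mean of C57 and DBA in both directions. Gal (0.70, adjusted p = 0.0107) and Gfap (0.40, adjusted p = 0.000238) rose more in CAST than in that mean. Against DBA alone Gfap rose less in CAST (−0.29, adjusted p = 0.0146), a call lost on the scale of log2(CPM + 0.5) (−0.21, adjusted p = 0.598), and Gal was not called (adjusted p = 0.44). Gpr151 differed by −1.96 on the log2 scale (SE 0.123, adjusted p = 5e-10), from 2.19 ± 0.247 to 26.0 ± 2.58 FPKM in CAST against 0.72 ± 0.297 to 61.1 ± 5.98 in C57 (SD, n = 4). Sprr1a differed by −1.38 (SE 0.214, adjusted p = 9.44e-05), the chemokine gene Ccl8 by −1.66 and carbonic anhydrase Car3 by −1.90. Car3 rose 16.5-fold in C57 and 4.06-fold in DBA (7.92-fold without naive DBA replicate 3) and stood at 1.04 ± 0.523 and 0.734 ± 0.338 FPKM in naive and injured CAST ganglia (SD, n = 4, adjusted p = 0.374). Thy1, a surface glycoprotein of neurons on the plus strand of chromosome 9 from 44043384 to 44048579, fell in CAST from 113 ± 2.57 to 67.0 ± 4.54 FPKM and rose in C57 from 114 ± 9.34 to 150 ± 10 and in DBA from 117 ± 7.7 to 158 ± 9.77 (SD, n = 4, interaction adjusted p = 1.67e-09). Cartpt, a neuropeptide precursor, changed in the opposite directions. It rose 1.99-fold in CAST and was 1.74-fold lower after crush in C57 and 1.69-fold lower in DBA. Klk4, a secreted protease, rose 31.6-fold in CAST, to 1.63 ± 0.17 FPKM (SD, n = 4), and the keratin gene Krt16 rose 22.8-fold, to 3.06 ± 0.306 FPKM (SD, n = 4). Krt16 rose more in CAST than in DBA on the log2 scale (1.60, adjusted p = 2.84e-13), a call lost with voom on estimated reads (1.024, SE 0.54, adjusted p = 0.26).

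Genes of the activin, BMP and TGF-beta pathway were listed with knowledge of the study, so they are not independent evidence. Inhba, which encodes the activin A subunit and lies on the plus strand of chromosome 13 from 16011851 to 16031621, rose from 0.00981 ± 0.00435 to 0.129 ± 0.0104 FPKM in CAST (SD, n = 4, 13.2-fold, adjusted p = 4.98e-16). In C57 it was at 0.00978 ± 0.00294 and 0.0102 ± 0.00305 FPKM (SD, n = 4, adjusted p = 0.934). In DBA it rose 1.99-fold (adjusted p = 0.0249), a call that was lost without injured DBA replicate 3 (adjusted p = 0.058), injured DBA replicate 4 (0.0612) or naive DBA replicate 4 (0.0642). On the scale of log2(CPM + 0.5) it was called in DBA (0.34, adjusted p = 0.00144). The response differed between CAST and the mean of the others (0.15 on the log2 scale, adjusted p = 1.8e-13), a difference that the scale compresses at such low FPKM and that was 1.97 ± 0.1 (SE) on the scale of log2(CPM + 0.5). Inhbb, the activin B subunit, rose from 0.824 ± 0.0739 to 6.56 ± 0.874 FPKM in C57, from 1.05 ± 0.132 to 9.61 ± 1.74 in CAST and from 0.686 ± 0.0953 to 8.54 ± 0.539 in DBA (SD, n = 4), with no difference called between CAST and the mean (adjusted p = 0.723). Follistatin (Fst), which binds activin, rose from 0.615 ± 0.213 to 4.41 ± 0.371 FPKM in CAST, from 0.368 ± 0.0743 to 5.93 ± 0.689 in C57 and from 0.336 ± 0.0321 to 9.7 ± 0.627 in DBA (SD, n = 4), less in CAST by −0.92 (adjusted p = 9.67e-07). Of the 37 genes, 5 responded more and 2 less in CAST, with 5 and 2 adjusted over the list alone (camera adjusted p = 0.327). Within strains 12 rose and 12 fell in C57, 16 and 10 in CAST and 16 and 12 in DBA (camera adjusted p = 0.835, 0.23 and 0.477), or 12 and 14, 16 and 11, and 17 and 13 adjusted over the list alone.

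The interaction was called for 3549 genes between CAST and C57 (2161 higher and 1388 lower), for 4225 between CAST and DBA (2186 and 2039) and for 4139 between CAST and the mean of both (2339 and 1800). With upper-quartile scaling more genes were lower than higher between CAST and DBA (1885 higher and 2350 lower) and between CAST and the mean (1945 and 2172). The split between CAST and DBA also turned with median-of-ratios scaling (2089 and 2161) and without injured DBA replicate 4 (1899 and 1911). With a minimum of 2-fold these were 93, 75 and 72. Atf3, Scn10a, Calca, Gap43, Jun and Sox11 were not called against the mean, with adjusted p-values from 0.312 for Jun to 0.988 for Sox11, which does not show that their responses were equal. The difference in the response of Npy between CAST and C57 was 1.11 on the scale of the test. It turned to −0.382 with voom on estimated reads (adjusted p = 0.663) and was lost with a pseudocount of 0.1 (adjusted p = 0.211) and on the scale of log2(CPM + 0.5) (adjusted p = 0.406).

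DBA and C57 were also compared with each other. Gal rose more in DBA than in C57, by 1.96 on the log2 scale (SE 0.209, adjusted p = 2.15e-06), and reached 340 ± 11.7 FPKM against 85.5 ± 9.18 (SD, n = 4). In CAST it reached 286 ± 33.5 FPKM (SD, n = 4), higher than in C57 in response (1.68, adjusted p = 8.99e-06) and not separable from DBA (−0.28, adjusted p = 0.44). Gfap (1.37), the peptide gene Ucn2 (1.73) and the synaptic organiser gene C1ql2 (1.51) rose more in DBA as well. The homeobox gene Hoxd10 fell in DBA from 2.98 ± 0.611 to 0.511 ± 0.11 FPKM (SD, n = 4) and stood at 2.75 ± 0.658 and 2.77 ± 0.217 in naive and injured C57 ganglia, and Scpep1, a carboxypeptidase, rose 4.89-fold in C57 and 1.58-fold in DBA. In all, 2443 genes were called, 1456 higher and 987 lower, of which 28 differed at least 2-fold. With voom on estimated reads the split turned to 944 higher and 1001 lower.

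Strains also differed before injury, which set the background for the responses. Of the Mas-related receptor genes of sensory neurons, Mrgprb5 stood at 51.6 ± 6.47 FPKM in naive CAST against 7.37 ± 1.71 in naive C57 ganglia, Mrgprb4 at 59.1 ± 0.835 against 9.09 ± 1.16 and Mrgpra4 at 5.69 ± 0.236 against 0.205 ± 0.0552 (SD, n = 4). Mrgpra2b, chosen after its values were seen, was lower in naive CAST by −1.07 on the log2 scale (adjusted p = 3.39e-14). The fucosyltransferase Fut1 on the plus strand of chromosome 7, from 45617289 to 45621059, was at 5.36 ± 0.348 FPKM in CAST and at 0.0535 ± 0.0145 in C57, and Sst was at 20.8 ± 1.64 against 3.77 ± 0.513 (SD, n = 4). Sprr1a was higher in naive CAST ganglia by 1.05 on the log2 scale (SE 0.175, adjusted p = 5.03e-05), and Sox11 by 0.63 (adjusted p = 6.46e-05). Values of CAST rest on reads aligned to mm10, the build named in the processing notes, and no CAST genome was used.

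Of 22 cholesterol synthesis genes, 17 were lower and 1 was higher in naive CAST than in naive C57 ganglia, also when adjusted over the list alone (camera adjusted p = 1.87e-05; adjusted p = 0.997 with an estimated correlation). Sc5d was lower by −0.62 and Idi1 by −0.58 on the log2 scale, and Lss was higher by 0.67. Of 14 antigen presentation genes, 9 were lower and 1 higher (camera adjusted p = 0.00348; adjusted p = 0.997 with an estimated correlation), with B2m at 10.3 ± 0.637 FPKM in CAST and 20 ± 2.91 in C57 (SD, n = 4). Of 21 interferon-response genes, 8 were lower and 1, Mx2, was higher (9 and 1 adjusted over the list alone, camera adjusted p = 0.0754, and 0.00391 on the scale of log2(CPM + 0.5)). Adipocyte genes had 7 of 9 higher (camera adjusted p = 0.0701, and 0.0346 on the same scale). With an estimated correlation the adjusted p was 0.997 for both lists, and the other lists had camera adjusted p-values of at least 0.159. In total 11892 genes were called between naive CAST and C57, 6517 higher and 5375 lower, a split that became 5413 and 6768 with upper-quartile scaling. With a minimum of 2-fold the count was 396, and 166 of these were lower.

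Between naive CAST and DBA 11965 genes were called (6417 higher and 5548 lower, and 363 at least 2-fold), a split that became 5353 and 6571 with upper-quartile scaling. Mrgprb4 was higher in CAST by 3.23 on the log2 scale (SE 0.135, adjusted p = 1.16e-13), and Klk8, a secreted protease, was lower by −1.72 (SE 0.047, adjusted p = 2.11e-16). Between naive DBA and C57 5769 genes were called (3007 higher and 2762 lower, and 157 at least 2-fold), or 2909 and 3004 with upper-quartile scaling. The split also turned with the filter on CPM (2443 and 2451), without the 3 libraries left out together (2747 and 2936), without naive C57 replicate 1 (2887 and 3172) and at a minimum of 2-fold (71 and 86). The potassium channel Kcnf1 was higher in DBA by 1.93 (SE 0.101, adjusted p = 1.1e-11), and Tmem45b was lower by −1.74 (SE 0.069, adjusted p = 1.55e-13).

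In injured ganglia, CAST was compared with the mean of C57 and DBA. Mx2, an interferon-induced GTPase on the plus strand of chromosome 16 from 97535308 to 97560900, was higher by 3.36 on the log2 scale (SE 0.088, adjusted p = 6.31e-17), at 12.6 ± 3.28 FPKM in injured CAST ganglia against 0.272 ± 0.0515 in C57 and 0.321 ± 0.0342 in DBA (SD, n = 4). Mrgprb4 remained higher after injury, by 2.59. Ccl8 was lower by −1.62, and the fatty acid binding protein Fabp7 of satellite glia by −2.05. In all 13683 genes were called, 7783 higher and 5900 lower, a split that became 5859 and 7997 with upper-quartile scaling, and 332 differed at least 2-fold.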

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

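Of 270 groups of 4 libraries that were tested for a library apart from the others, 19 held one, and chance alone gives about 1 in 20 groups. Mean log2(FPKM + 1) of injury-induced transcription factors was 2.3 in injured C57 replicate 1 (2.2 to 2.22 in the others), and that of growth-associated genes was 3.79 there (3.65 to 3.67) and 3.77 in injured CAST replicate 3 (3.64 in the others). On the same scale, nociceptor genes stood at 1.92 in injured DBA replicate 2 (1.82), interferon-response genes at 0.86 in injured DBA replicate 3 (0.61 to 0.64), and skeletal muscle genes at 0.23 there (0.15 to 0.17). In naive DBA replicate 3, cell cycle genes stood at 0.25 (0.19 to 0.2) and macrophage genes at 0.63 (0.49 to 0.51). Neutrophil genes were at 0.84 (0.44 to 0.5) and oligodendrocyte, astrocyte and spinal cord genes at 0.08 (0.06) in injured CAST replicate 1, and handling-stress genes at 2.73 (2.62 to 2.64) in injured DBA replicate 1.

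Single genes were apart in these libraries, in FPKM: Sprr1a at 1.29 in naive C57 replicate 1 (0.318 to 0.483), Jun at 64 in injured CAST replicate 3 (51.5 to 52.8), Sox11 at 2.03 in naive DBA replicate 4 (2.28 to 2.31) and Gal at 323 in injured DBA replicate 3 (345 to 347). Vip was at 0.00833 in naive CAST replicate 2 (0 in the others), Scn10a at 3.31 in injured DBA replicate 2 (2.73 to 2.81) and Gfap at 2.96 in injured DBA replicate 1 (2.17 to 2.23). The library total of naive C57 replicate 4 was 107.6 M reads (96 to 97.9).

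Responses to crush differed between strains by a test of the interaction, for 3549 genes between CAST and C57, 4225 between CAST and DBA, 2443 between DBA and C57, and 4139 between CAST and the mean of the others. Against that mean, the median log2 difference was 0.8 for interferon-response genes, 0.61 for antigen presentation genes, 0.14 for macrophage genes and −0.1 for cholesterol synthesis. Single genes differed by −1.38 (Sprr1a), 0.7 (Gal), 0.57 (Npy), 0.15 (Inhba), −0.92 (Fst) and 0.4 (Gfap). The difference of Npy was lost with a pseudocount of 0.1 (0.183, adjusted p = 0.684) and on the scale of log2(CPM + 0.5) (0.111, adjusted p = 0.838), and turned to −0.328 with voom on estimated reads (adjusted p = 0.586).

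Among the splits of the same libraries only the real one, 1 split, reached each count of called genes. A random assignment of libraries therefore rarely gave as many, though no share below 1 in 35 or 1 in 100 could be reached. The other splits mix libraries of different groups, which widens the spread, so they do not show how many calls are false. For the response to crush the real count and the highest other were 10449 and 2935 in C57, 12754 and 97 in CAST, and 13563 and 6 in DBA, each over 35 splits. For the interactions, over 100 splits, they were 3549 and 1299 (CAST and C57), 4225 and 1297 (CAST and DBA), 2443 and 3 (DBA and C57), and 4139 and 968 (CAST and the mean). For naive ganglia, over 35 splits, they were 11892 and 4 (CAST and C57), 11965 and 21 (CAST and DBA), and 5769 and 24 (DBA and C57). For injured CAST against the mean they were 13683 and 6772, and for the response shared by the 3 strains 7262 and 0, each over 100 splits.

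The first pattern weighed is the larger rise of interferon-response genes in CAST, where the test of macrophage numbers was chosen only after the result was seen. The macrophage list differed by a median of 0.48 (SE 0.12) against 2.47 (SE 0.49) for the interferon list, both in log2 CPM. These SEs come from resampling the genes of a list and do not measure the spread between animals. Single injured CAST libraries stood at 3.46 to 3.85 for the macrophage list, against 3.53 to 3.73 in DBA and 3.21 to 3.45 in C57. For the interferon list they stood at 3.95 to 4.95, against 2.29 to 2.9 and 2.36 to 2.99. These values argue against more macrophages as the whole cause. The rise was not confined to single animals, such as infected ones. The lowest injured CAST library lay 2.14 above the highest naive one on the log2 scale. Injured CAST replicates 1 and 2 stood at 4.83 and 4.95 for the interferon list, and replicates 3 and 4 at 3.95 and 4.1. Whether single animals added to the size of the rise was not tested. A strain variant that hides reads would act in naive and injured CAST ganglia alike, and 20 of the 21 genes differed in response with voom on estimated reads. An exposure shared by all 4 injured CAST animals stays open.

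The second pattern is the set of genes that differed at least 2-fold on the log2(FPKM + 1) scale between naive CAST and C57, where the matched random sets, the part on families holding under 20% and both tests of strain variants were chosen only after the result was seen. A copy of a gene held at least 20% of its 31-mers. Of 368 genes with a transcript and a span, 58.4% had a copy, against a mean of 45.3% and a maximum of 51.9% in 1000 random sets matched on span and level, so genes with copies were in excess. Counted reads that move between copies leave the family total as it was. Reads dropped for mapping to several places would not, and the treatment of such reads is not given. Among genes that held 20% or more of the reads of their family, 30.8% had a family total within 2-fold (34.3% without the 8 genes that held at least 95% of their family). Genes of 1 family share a total, so these genes are not independent. Genes with no copy among the measured genes had no family total to test and were left out. Counted reads moved within a family do not account for totals beyond 2-fold. They stay open for the 24 genes whose total lay within 2-fold. Of 123 genes that held less, 36 had a family total at least 2-fold apart in the same direction, without overlap of libraries, and 22 of the 36 were copies of SNORD116. Counted reads moved within a family cannot give those totals. Dropped shared reads stay open, and which copy differed was not tested. For the other 87, such as Gapdh (1.9% of its family, log2 difference −2.15 alone and −0.26 for the family), the data cannot tell. For 79 genes with no shared 31-mer, reads shared between the longest transcripts are excluded. Introns, other transcripts and sequence outside annotated genes were not searched. A loss of CAST reads at variants lowers CAST values, so it cannot account for the 46 of these genes that were higher in CAST. This follows from their direction alone, and other effects of aligning CAST reads to mm10 were not tested. For 166 genes lower in CAST the data cannot tell, since no CAST genome was used.

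The third pattern is the rise of Inhba in CAST, where the tests of counting noise and of a strain variant were chosen only after the result was seen. CPM in injured CAST was 7.05 times that in injured DBA, with a lower 95% Poisson bound of 5.97, so counting noise is excluded. Injured over naive CAST ganglia gave 13.3, with a lower bound of 10.6, in 1 strain and against the same reference. The largest median difference of a cell type list was 0.76 (skeletal muscle) against 1.97 (SE 0.1) for Inhba. Naive DBA replicate 3, which held skeletal muscle transcripts, enters that muscle value. An even rise of all cells of a listed type would therefore be too small to account for Inhba. A list median does not bound a subset of such cells, so a gain of cells of a listed type is not excluded. Inhba was chosen with the study in mind, and a cell type without a list was not tested.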

How the results depend on the processing

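Every count of called genes stayed within 1.5 times its main value under each other scaling, filter, pseudocount and choice of groups. The genes called were not always the same. Voom on estimated reads, with 26140 genes tested, kept 2202 of 3549 interaction calls for CAST and C57 and 2739 of 4225 for CAST and DBA. It kept 1561 of 2443 for DBA and C57 and 2636 of 4139 for CAST and the mean. For crush in C57 it kept 9814 of 10449. Leaving out 1 library at a time gave 9252 to 10920 genes changed by crush in C57, 11813 to 12191 in CAST and 12517 to 12904 in DBA. It gave 3063 to 3804 for CAST against C57 in response, 3687 to 4158 for CAST against DBA, 1941 to 2747 for DBA against C57 and 3630 to 4465 for CAST against the mean. The naive comparisons gave 10887 to 11851, 11046 to 11186 and 4877 to 6059, injured CAST 12436 to 13620 and the shared response 6651 to 7463. With a minimum of 2-fold on the log2(FPKM + 1) scale, which by construction keeps fewer genes, the counts fell to 147, 296 and 309 for crush in C57, CAST and DBA, to 93, 75, 28 and 72 for the interactions in the order above, to 396, 363 and 157 for naive ganglia, to 332 for injured CAST and to 95 for the shared response. Of 130 gene list tests against all other genes 50 were called, and 9 with an estimated correlation between genes, which widens the null of lists whose genes move together. Fry tests a list against no change, which is another question, and called 73. Camera called no direction for the neurotrophic factors in crushed C57 ganglia (adjusted p = 0.838), and fry called them higher (adjusted p = 0.00428), so no call was turned. With voom on estimated reads, Npy reversed for CAST minus C57 (−0.382), DBA minus C57 (−0.109) and CAST minus the mean (−0.328). Naive libraries held 0.0328 to 0.328 FPKM of Npy, below the 1 that is added before the log. With 0.1 added, the difference was 0.528 for CAST minus C57 (limma adjusted p = 0.211) and 0.691 for DBA minus C57 (0.102). The calls for Npy thus depended on the value added and do not show a strain difference in its fold. Voom, log2 of CPM plus 0.5 and the fit without 3 libraries were chosen after seeing the data. The planned test designed for raw counts was not run, because the values are FPKM. The paired fit with a replicate block gave 9886, 12191 and 13075 genes for crush and 6846 shared. It called interferon-response genes in DBA (camera adjusted p = 0.0422) and lymphocyte genes in C57 (0.0477) and DBA (0.0447). None of these lists was called with an estimated correlation without the block (0.747, 0.579 and 0.604). The values did not show that replicate numbers pair libraries (r from −0.3 to 0.271 between equal numbers, and 4 of 12 best with their own number). With 4 libraries per group this check cannot exclude pairing.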

Other observations

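The neurotrophic factor gene Gdnf rose in DBA from 0.00722 ± 0.00169 to 0.139 ± 0.0216 FPKM and in CAST from 0.0189 ± 0.0038 to 0.0669 ± 0.0271, and stood at 0.0115 ± 0.00295 and 0.0124 ± 0.00241 in naive and injured C57 ganglia (SD, n = 4). Its response was larger in DBA than in C57 (adjusted p = 1.67e-06). The endopeptidase gene Ecel1 of injured neurons rose 116-fold, 53-fold and 124-fold in C57, CAST and DBA, with no interaction called between CAST and the mean (adjusted p = 0.682). On the scale of log2(CPM + 0.5), chosen after seeing the data, it was called (−0.55, adjusted p = 0.0357). The serotonin receptor gene Htr3a fell in each strain and was 2.19-fold, 4.2-fold and 6.57-fold lower. Its fall was larger in DBA than in C57 (−0.95 on the log2 scale, adjusted p = 1.89e-06). Tmem88b, a membrane protein gene, rose from 0.617 ± 0.158 to 7.72 ± 1.04 FPKM in C57 and from 0.618 ± 0.0536 to 2.02 ± 0.136 in DBA (SD, n = 4), less in DBA by −1.53 (adjusted p = 7.16e-08).

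Cell cycle genes were low in all groups. Top2a, which separates replicated DNA, rose 2.07-fold, 3.78-fold and 6.1-fold in C57, CAST and DBA, more in DBA than in C57 (adjusted p = 0.000103). Irf7, a transcription factor of the interferon response, rose from 0.0525 ± 0.0047 to 1.6 ± 0.653 FPKM in CAST (SD, n = 4) and was not called in C57 (adjusted p = 0.783) or DBA (adjusted p = 0.381).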
